A study of Mus musculus with 6 samples.

How the data were processed

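Each array compared 2 fibre cultures directly. Per the labels' protocols, fibres from CD-1 mice aged 4 to 5 weeks were infected in culture and RNA of over 100 fibres per extract was taken on day 3 and amplified. The deposited scanner files hold spot and background intensity on a linear scale for 144 spots per array and dye, per the file headers, and the scanning software's name was not given in the sources used here. The deposited value table holds a linear ratio per spot for 132 rows and 6 arrays. Per the labels, each gene had 6 spots whose mean the submitters used. Set against the scanner values, the table came near Cy3 over Cy5 of the background-subtracted medians, up to a shift per array. The match was inexact, with best r within probe sets of 0.49 to 0.93. Background means in place of background medians did as well in some columns, so the formula is approximate. The shift ran from -0.28 to 0.27 on the log2 scale. How that shift was chosen stays unknown. The column medians lay between 0.911 and 1.13.

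The scanner files name no gene. Spots were named by matching values with the table, whose probes carry a gene symbol in 20 of 22 sets; 2 sets are unnamed here, no probe had several symbols, and 19 symbols were matched by Entrez ID to a RefSeq table of assembly GRCm38.p6, used for names alone. Of 2256 ordered pairs of spot positions, the chosen pair ranked first by median or mean difference for 17 of 18 placed sets and by both for 14. The exception was Calm2, at ranks 2 and 4 and at 435 on experiment 1 alone, so its name is uncertain. Myh7 and Mgp ranked first by the median alone, at ranks 158 and 7 by the mean. Positions were chosen by closeness of these same values, so a first rank was largely fixed in advance. The ranks also set the columns of experiments 2 and 3 against the partner arrays described below. On experiment 1 alone, 9 of 17 sets ranked first. The rest, Calm2 apart, ranked 2 to 14 there, with Acta1 at 5 and Tnni2 at 14, so the names of these sets are less firm. Myh6 and CAMTA1 had no table values, and Pln and Csrp3 had 4 and 6, so these 4 sets were not placed and not analysed here.

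Which array lies behind each value column was examined with 6 pairs of signal and background columns over the 7 complete sets that ranked first on experiment 1 alone. In 24 of 24 cases in experiments 2 and 3 the column correlated better, within probe sets, with the partner array of the swap than with its own. These cases are 4 columns under 6 overlapping choices on the same spots, so they are not independent. Over 13 complete sets the best matches had r between 0.49 and 0.93, and own files in experiments 2 and 3 between -0.32 and -0.25. Neither labels nor headers settle which source carries the exchanged labels. The record of which file belongs to which sample was kept for all main values. Turning experiments 2 and 3 was added after the data were seen, after the experiments had been found to oppose each other, so their closer match once turned is no independent evidence for that direction.

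Intensities were background-corrected in limma 3.58.1 (R 4.3.3) with normexp and an offset of 50, fitted on all spots, and log ratios were normalized by loess with weight 0 for spots outside the placed sets. The 6 spots of a set were averaged, arrays were turned to calcineurin over control, and both arrays of a swap were averaged to 1 value per experiment. The experiment number comes from the labels, which tie the 2 arrays of a swap together. lmFit and eBayes tested the mean of 3 experiments against 0, two-sided, with Benjamini-Hochberg adjustment over 18 sets and a threshold of 0.05. Array scans were grouped by experiment, and both cultures were on every array. Camera with a preset correlation of 0.01 and with an estimated one, and fry, were run on lists with at least 2 members, against a background of the 18 muscle-chosen sets. Because most of these sets are muscle genes, loess can remove part of a real difference.

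The tests were fixed before the data were examined, as was the rule for named genes. It took up to 15 genes in each direction past the threshold, the 10 smallest p where fewer than 10 passed, every measured member of the slow, fast and calcineurin lists, the 2 widest members of other lists, and cell type markers. Mgp and set 17 fall outside the rule and were chosen after their values were seen. The planned design expected gene names in the scanner files, and the matching of spots departs from it. Alternatives covered background correction, pixel summary, normalization, dim and marked spots, spot summary, a replicate block with a dye term, single orientations, the authors' table, moderation and each experiment left out. The fit was tested on simulated data, 200 panels of 18 genes with 6 changed. With an SD of 0.3 between experiments it recovered 51.4% of changes of 0.5 and 98.9% of changes of 1 on the log2 scale. With an SD of 0.5 it recovered 10.8% and 76.7%, and with an SD of 1 it recovered 1.58% and 9.0%. As recorded, 9 of the 18 sets had an SD above 0.3, and the SDs ran from 0.020 to 1.04. Simulated genes were independent and shared 1 SD per panel, so these recovery rates need not hold for the real sets.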

Results

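Messenger RNA of cultured mouse flexor digitorum brevis fibres, a fast muscle of the foot, was compared between fibres expressing constitutively active calcineurin and control fibres. Calcineurin is a calcium-activated phosphatase that acts on NFAT transcription factors. Treated fibres carried adenoviruses for the active phosphatase and for NFAT joined to green fluorescent protein, and control fibres carried the NFAT virus alone. The series held 3 independent experiments, each hybridised as a dye swap of 2 arrays, so 6 arrays gave n = 3. Each array carried 22 probe sets of 6 spots in the value table, of which 18 could be located on the scanner images, 16 of them with a gene name. The median signal over background per array and channel lay between 6.17 and 32.8. For arrays of this kind their number, 3 experiments, limits the precision.

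The direction of the ratio was unsettled in experiments 2 and 3. With each scanner file under the sample that records it, the log2 ratios of active calcineurin over control in experiment 1 correlated across the 18 probe sets with those of experiment 2 at r = -0.51 and of experiment 3 at r = -0.51, while experiments 2 and 3 correlated at r = 0.87. In the authors' value table the corresponding values were 0.29, 0.76 and 0.57, where those with experiment 1 leave out Ppp2ca, which had no value there. Genes are not independent replicates, so these coefficients carry no p-value. The value columns of experiments 2 and 3 followed the spot pattern of the other array of the same swap, and those of experiment 1 followed their own. Main signed values from the scanner files are therefore given as recorded and also with experiments 2 and 3 turned. Values from the authors' table are given under its own labels alone, whose direction in experiments 2 and 3 is equally unsettled. The 2 turned arrays of a swap correlated at r = 0.84, 0.64 and 0.77 in experiments 1, 2 and 3.

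The main comparison asked which genes differed between fibres with active calcineurin and control fibres. With the files as recorded, Pvalb, a calcium buffer of fast fibres, had a mean log2 ratio of 0.54 ± 0.30 (SD, n = 3), and with experiments 2 and 3 turned it was -0.39 ± 0.55. Its sign in experiment 1 also turned with the normalization, from 0.24 after loess to -0.46 with median centring, where the mean as recorded was 0.30. Calm2, a calmodulin gene whose spots were placed with less certainty, stood at -0.37 ± 0.26 (SD, n = 3) as recorded and -0.064 ± 0.52 turned. Myh7, the slow myosin heavy chain, stood at -0.23 ± 0.17 (SD, n = 3) as recorded and -0.025 ± 0.33 turned, and at -0.012 as recorded without the spots marked by the scanner software. Neither these nor any other of the 18 probe sets passed limma with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.388. The count was 0, with 1 probe set, Pvalb, at an unadjusted p under 0.05. With experiments 2 and 3 turned the count was again 0, with 6 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.114.

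The unnamed probe sets 4 (probes 19 to 24) and 17 (probes 97 to 102) had the widest differences after loess in experiment 1, whose labels were the same in both sources. Set 4 stood at 1.39 and set 17 at 1.22 on the log2 scale, higher in fibres with active calcineurin. In experiments 2 and 3 as recorded, set 4 was at -0.37 and -0.39, and set 17 at -0.63 and -0.53. With these experiments turned, the means were 0.72 ± 0.58 (SD, n = 3) for set 4 and 0.79 ± 0.37 (SD, n = 3) for set 17. Experiments 2 and 3 ran the same way in either reading. Fitted without experiment 1, so with n = 2, limma passed 4 probe sets. The adjusted p was 0.0337 for sets 4 and 17 and 0.0366 for Pvalb and Ldhb. Their sizes were 1.30-fold for set 4, 1.49-fold for set 17, 1.62-fold for Pvalb and 1.22-fold for Ldhb, with no settled direction. This fit drops the experiment that opposed the others, and 12 of 18 sets had an unadjusted limma p under 0.05 in it. As recorded, leaving out experiment 2 or experiment 3 instead passed 0.

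**Figure D1:**
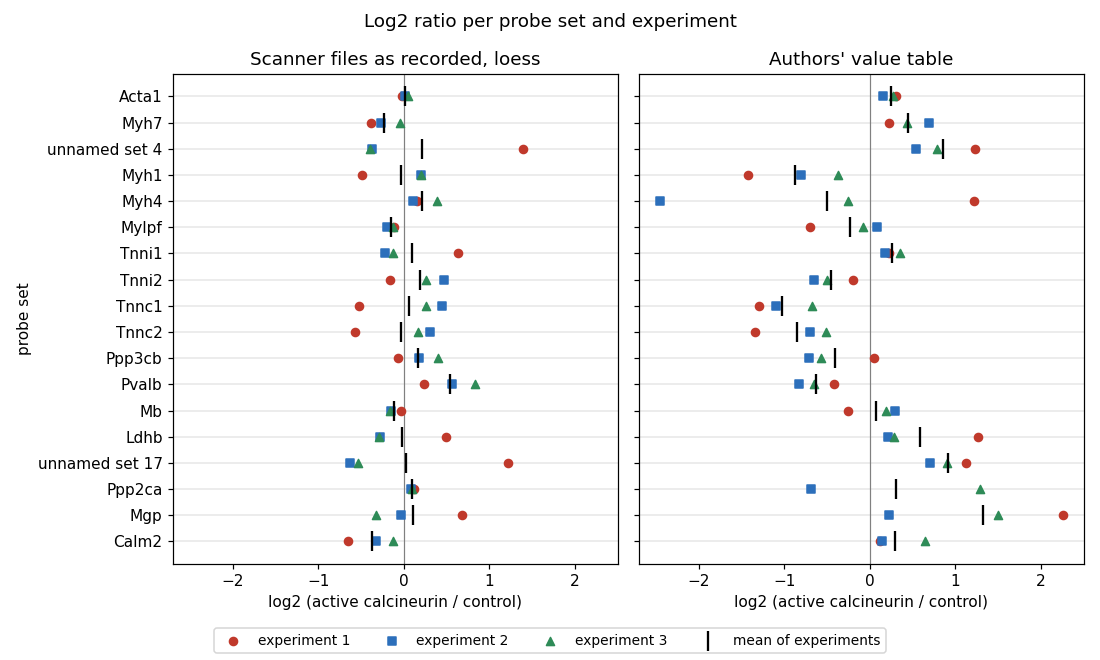
Log2 ratio of active calcineurin over control (x axis) for each of 18 probe sets (y axis), with 1 point per experiment and a black tick at their mean. On the left, with scanner files as recorded and loess, experiment 1 lies opposite to experiments 2 and 3 for set 17 (1.22 against -0.63 and -0.53). On the right, in the authors' value table under its own labels, the 3 experiments lie on the same side for set 17 (1.12, 0.71 and 0.90). Ppp2ca has no point for experiment 1 there.

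The list of fast-fibre genes had 6 measured members of 15, Myh1, Myh4, Mylpf, Tnni2, Tnnc2 and Pvalb, and none passed, either over all genes or adjusted over the list alone. Its median log2 ratio was 0.078 with the files as recorded and -0.30 with experiments 2 and 3 turned. In experiment 1, the fast myosin heavy chain Myh1 stood at -0.49 and the fast troponin C gene Tnnc2 at -0.57, while experiments 2 and 3 as recorded gave 0.20 and 0.20 for Myh1 and 0.30 and 0.17 for Tnnc2. These sizes depended on loess. With median centring as recorded, experiments 1, 2 and 3 gave -1.35, 0.63 and 0.39 for Myh1 and -1.36, 0.58 and 0.48 for Tnnc2. The authors' table gave -1.42 and -1.34 for these genes in experiment 1. Myh1 and Tnnc2 had the widest falls of the list in experiment 1 after loess. Mylpf stood at -0.12, -0.20 and -0.13 in experiments 1, 2 and 3 as recorded, and Tnni2 at -0.16, 0.47 and 0.26. Myh4, at 0.15, 0.11 and 0.39, and Pvalb, at 0.24, 0.56 and 0.83, were above 0 in each experiment as recorded. Camera with a preset correlation of 0.01 gave p = 0.354 for the list by limma as recorded and p = 0.0258 turned, the latter at a false discovery rate of 0.0774. With an estimated correlation the limma camera p was 0.571 as recorded and 0.130 turned. The estimates were 0.32 and -0.20, so the larger turned p is no sign of correlation among the list's genes. Fry in limma, which asks whether a list's genes move one way on balance and compares them with no other genes, gave an adjusted p over 3 lists of 0.560 as recorded and 0.00279 turned.

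Of 15 listed slow-fibre genes 3 were measured, Myh7, Tnni1 and Tnnc1, and none passed. Tnni1, the slow troponin I gene, was at 0.63 in experiment 1 and at -0.22 and -0.12 in experiments 2 and 3 as recorded. Tnnc1, the slow and cardiac troponin C gene, went with Tnnc2, at -0.52 in experiment 1 and at 0.44 and 0.26 in experiments 2 and 3. With median centring as recorded, experiments 1, 2 and 3 gave -1.34, 0.82 and 0.63 for Tnnc1 and 0.053, -0.13 and -0.23 for Tnni1. In experiment 1 the authors' table gave -1.30 for Tnnc1 and 0.23 for Tnni1. The list median was 0.062 as recorded and -0.025 turned, and as recorded its sign turned with median centring, to -0.10, and with no normalization, to -0.037. No slow member passed adjusted over the list alone as recorded, and 1 did so turned, Tnnc1 at -0.41, lower with active calcineurin. The limma camera p was 0.472 as recorded and 0.817 turned, or 0.535 and 0.834 with an estimated correlation, and fry gave an adjusted p of 0.560 and 0.242.

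The slow minus fast difference, taken between the means of the 2 lists, asked whether the fibre programmes parted. It was 0.072 in experiment 1 and -0.26 and -0.25 in experiments 2 and 3 as recorded, a mean of -0.15 ± 0.19 (SD, n = 3) with p = 0.5 in a two-sided exact sign-flip permutation test. Without the spots marked by the scanner software the mean was -0.059. Turned, the mean was 0.19 ± 0.11 (SD, n = 3) with exact p = 0.25, the smallest that 3 experiments allow. Turned, it was 0.10 without the marked spots and 0.32 with plain background subtraction. Between list medians, chosen after seeing the data, experiment 1 stood at -0.24, and the mean was -0.33 ± 0.13 as recorded and 0.17 ± 0.37 turned, so the turned experiments did not share a sign. With median centring and list means the turned experiments stood at 0.14, 0.32 and 0.34. Under its own labels the authors' value table gave 0.20, 0.82 and 0.43 in experiments 1, 2 and 3. The mean was 0.48 ± 0.32 (SD, n = 3), also with exact sign-flip p = 0.25. Within its fast mean, dim Myh4 stood at 1.22, -2.46 and -0.25. Between list medians it gave 0.84 ± 0.082, where the slow median was set by Myh7 or Tnni1 and passed over Tnnc1, at -1.02. Turning experiments 2 and 3 of that table would put them opposite to experiment 1 by either measure.

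Among the remaining lists, oxidative metabolism had 2 measured members of 51, Mb and Ldhb. Ldhb, the heart-type lactate dehydrogenase subunit, stood at 0.49 in experiment 1 and at -0.27 and -0.29 in experiments 2 and 3 as recorded, and Mb, myoglobin, at -0.031, -0.15 and -0.16. The list median was -0.069 as recorded and 0.22 turned, with limma camera p of 0.305 and 0.158, or 0.520 and 0.275 with an estimated correlation. Fry in limma gave this pair an adjusted p of 0.560 as recorded and 0.00157 turned. Turned, Mb was lowest in experiment 1, where Ldhb was highest, and their estimated correlation was -0.99. The list median was thus nearly constant, at 0.23, 0.21 and 0.23 in experiments 1, 2 and 3. The small fry p rests on 2 genes that offset each other, and Mb alone averaged 0.094. With Ldhb alone past the list-wide adjustment turned, the count adjusted over the list alone was 1, and as recorded it was 0. Ppp3cb, the beta catalytic subunit of calcineurin, was the measured member of the calcineurin list and stood at 0.17 ± 0.23 (SD, n = 3) as recorded and -0.21 ± 0.17 (SD, n = 3) turned. As recorded it was 0.32 with median centring and 0.39 with no normalization. Ppp3ca and Rcan1 were not among the placed sets, so the label check they were meant to give was not made, and whether the Ppp3cb spots see the viral form is unknown. Acta1, skeletal actin, was at 0.013 ± 0.030 (SD, n = 3) as recorded and -0.024 ± 0.016 turned, and its brightest spot read 62486, near the top of the scanner's range, where ratios are compressed. Ppp2ca stood at 0.10 ± 0.020 (SD, n = 3) as recorded and -0.018 ± 0.12 turned, and Mgp at 0.11 ± 0.51 (SD, n = 3) as recorded and 0.34 ± 0.32 turned. Both depended on the background step, since plain subtraction gave 0.54 for Ppp2ca and 0.65 for Mgp as recorded. Ppp2ca and Myh4 reached 2 times background in Cy3 on 2 and 3 of 6 arrays, so their ratios rest on dim spots. The developmental, myogenic, glycolytic, growth and reference lists, and every cell type marker list, had 0 placed members.

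Scanner spots were placed by closeness to the authors' value table, and experiments 2 and 3 were turned to follow its columns. Its ratios lay on the same side as the turned reading for 12 of 17 probe sets in experiment 1, 17 of 18 in experiment 2 and 15 of 18 in experiment 3. That sharing was largely fixed in advance, so it is no evidence for the turned direction. In experiment 1, which no relabelling touches, Myh7 was at -0.38 after loess and at 0.23 in the table, and Pvalb at 0.24 and -0.42. With median centring they stood at 0.096 and -0.46, on the table's side, and experiment 1 correlated with the table across 17 sets at r = 0.98, against 0.73 after loess, with 15 signs shared. Median centring only shifts each array, and the table lay near the scanner ratios up to such a shift. Its closer match was thus largely built in, and it cannot tell which normalization or sign is right. In the table under its own labels, Tnnc1 was at -1.02 ± 0.32, Myh1 at -0.87 ± 0.53, Tnnc2 at -0.85 ± 0.44 and Pvalb at -0.63 ± 0.20 (SD, n = 3). Each was lower with active calcineurin in 3 of 3 experiments, but would be lower in experiment 1 alone were experiments 2 and 3 turned. Mgp had the largest mean, 1.32 ± 1.03 (SD, n = 3), higher in 3 of 3, but it rests on dim spots. Its median signal over background was 2.23 in Cy3 and 2.17 in Cy5. The scanner software marked 14 of its 36 spots, and the table held 27 values for it. Set 17 was at 0.91 ± 0.21, set 4 at 0.85 ± 0.35, Ldhb at 0.58 ± 0.59 and Myh7 at 0.45 ± 0.24 (SD, n = 3), higher in 3 of 3. Were experiments 2 and 3 of the table turned, Mgp and these sets would be higher in experiment 1 alone. Under the table's own labels no set passed limma with Benjamini-Hochberg adjustment, with 7 sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.0526. Camera gave the fast list p = 0.00281 at a false discovery rate of 0.00844, and the call was lost with an estimated correlation, at p = 0.0684. Fry in limma gave an adjusted p of 0.0558 for the fast list, 0.0234 for the oxidative list and 0.609 for the slow list. The oxidative list rested on 2 genes, of which Mb averaged 0.074 and stood at -0.26 in experiment 1, and limma camera gave it p = 0.462, or 0.528 with an estimated correlation. Adjusted over the list alone, the fast genes Myh1, Tnnc2 and Pvalb passed, and so did 1 slow gene, Tnnc1, all 4 lower with active calcineurin. These calls and directions rest on the table's labels, since turning experiments 2 and 3 would set experiment 1 opposite to the others for each gene.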

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

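The 2 alternatives that relabel experiments 2 and 3, and list medians for the slow minus fast difference, were chosen after seeing the data, and the others were fixed beforehand. The count of 0 probe sets past the threshold held in every alternative with the files as recorded, the authors' value table included, except without experiment 1. With a replicate block and a dye term on 6 arrays the count as recorded was also 0. Turned, that fit passed 2 sets against 0, sets 4 and 17 at a limma adjusted p of 0.0458. It brings a replicate block, a dye term and 6 arrays in place of 3 swap averages together, and the averages already keep the pairing, so the block alone was not tested. Centring on reference genes was not run, since no reference gene was placed. With experiments 2 and 3 turned, 7 of 13 further alternatives, leaving out experiments apart, also gave 0, and the highest count was 6. Turned, the count was 4 without experiment 1, 2 without experiment 2, sets 4 and 17 at a limma adjusted p of 0.0263, and 0 without experiment 3. For every shift below the cause was not tested.

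Leaving out each experiment in turn gave 0 to 4 probe sets and a slow minus fast difference of -0.25 to -0.090. The slow median lay between -0.15 and -0.039, against 0.062 with all experiments, the fast median between -0.040 and 0.24, against 0.078, and the oxidative median between -0.22 and 0.0097, against -0.069. Log2 ratios ranged from -0.38 to 0.51 for set 4, -0.58 to 0.34 for set 17, -0.15 to 0.20 for Myh1, -0.17 to 0.26 for Tnni1, -0.20 to 0.24 for Tnnc2, -0.13 to 0.35 for Tnnc1, -0.28 to 0.11 for Ldhb, -0.18 to 0.32 for Mgp, 0.055 to 0.28 for Ppp3cb, 0.046 to 0.36 for Tnni2, 0.40 to 0.70 for Pvalb, -0.49 to -0.23 for Calm2, -0.32 to -0.15 for Myh7 and -0.0025 to 0.028 for Acta1.

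Plain background subtraction moved Calm2, the lone member of the excitation list, to -0.96, and gave Myh7 -0.58, Ppp2ca 0.54, Mgp 0.65 and a slow minus fast difference of -0.30. Normexp with offset 0 gave Ppp2ca -0.35. The median of spot pixels gave Acta1, the lone member of the sarcomere list, 0.045. Median centring without loess gave a slow median of -0.10, Ppp3cb 0.32, Acta1 -0.063, Tnni1 -0.10, Ldhb 0.22 and set 17 -0.13. No normalization gave a slow median of -0.037, Ppp3cb 0.39, Tnni1 -0.037, Ldhb 0.28 and set 17 -0.067. Without the spots marked by the scanner software Acta1 was at -0.012, Myh7 at -0.012, the fast median at 0.034 and the slow minus fast difference at -0.059. The arrays with calcineurin in Cy3 gave Tnnc1 -0.0042 and Ldhb 0.099, and those with calcineurin in Cy5 gave Tnnc2 0.0062 and set 17 -0.13.

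Under its own labels, the authors' value table gave a slow minus fast difference of 0.48 and medians of 0.25 for the slow, -0.57 for the fast and 0.33 for the oxidative list. It gave Mgp 1.32, Acta1 0.24, Myh7 0.45, Myh4 -0.50, Tnni2 -0.45, Tnnc1 -1.02, Ppp3cb -0.41, Pvalb -0.63, Mb 0.075, Ldhb 0.58 and Calm2 0.30.

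Turning experiments 2 and 3 gave a slow minus fast difference of 0.19 and medians of -0.30 for the fast and 0.22 for the oxidative list. It gave Acta1 -0.024, Myh4 -0.12, Mylpf 0.069, Tnni2 -0.30, Tnnc1 -0.41, Ppp3cb -0.21, Pvalb -0.39, Mb 0.094, Ldhb 0.35, Ppp2ca -0.018 and Calm2 -0.064.

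Turning them together with median centring without loess passed 6 probe sets in limma, sets 4 and 17 higher and Myh1, Tnnc1, Tnnc2 and Pvalb lower. This changes 2 choices at once and gave the highest count of the turned settings, so it is 1 of several outcomes and not a better estimate. The slow minus fast difference was 0.27, with medians of -0.53 for the fast and 0.20 for the oxidative list. It gave Acta1 0.12, Myh7 0.20, Tnni2 -0.45, Tnnc1 -0.93, Ppp3cb -0.33, Pvalb -0.60, Ldhb 0.41, Ppp2ca -0.0035 and Calm2 0.17. Signal over background limits Ppp2ca, Myh4, Mgp, Calm2 and Myh7, the dimmest sets.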

Other observations

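All tests of explanations in this part except the count of sign patterns were chosen after the values they bear on had been seen.

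Experiment 1 ran opposite to experiments 2 and 3 with the scanner files as recorded for 11 of 18 sets, among them the unnamed sets 4 and 17, Tnnc1, Mgp and Tnni1, while Myh7, Myh4, Mylpf, Pvalb, Mb, Ppp2ca and Calm2, 7 sets, had the same sign in all 3. A candidate explanation is that the 2 arrays of a swap carry exchanged labels in experiments 2 and 3, either in the files or in the value table: 24 of 24 column and intensity choices followed the partner array. Those choices are 4 value columns under 6 overlapping intensity pairs, not independent cases. This hypothesis was found and tested on the same data, and it does not say which source is right. An opposite response of the fibres in experiment 1 stays open, since its test rests on labels that are themselves in question. Within a single dye orientation and over the 13 complete sets, the value columns of experiment 1 correlated with the others at 0.66 or more. Over 17 sets, swaps averaged, the values were 0.29 with experiment 2 and 0.76 with experiment 3. Ppp2ca had no value in experiment 1, and dim Myh4 stood at 1.22 in experiment 1 and -2.46 in experiment 2.

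Tnnc1 is a slow-fibre gene, yet its ratios lay beside those of the fast gene Tnnc2. Transcripts of Tnnc2 bound to the Tnnc1 spots could give this: the size of the Tnnc1 log2 ratio exceeded that of Tnnc2 by 0.061 with an SD of 0.098 over 3 experiments. The test compares sizes without sign, and 4 of the 5 other fast genes also lay within 1 SD of Tnnc1 in size. Among them Pvalb, at 0.24, and Myh4, at 0.15, ran opposite to Tnnc1, at -0.52, in experiment 1. It therefore cannot part a shared signal from a shared change.

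The count of 0 probe sets for active calcineurin was set against the sign patterns of 3 experiments. All 4 patterns gave 0, the highest other included. With a real count of 0 every pattern gives at least as many, so the comparison decides nothing, and 4 patterns are too few for a share under 0.05.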
